A study of Homo sapiens with 12 samples.

How the data were processed

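Poly(A) RNA libraries (TruSeq mRNA) were made from total RNA extracted with TRIZOL from Ishikawa cells carrying a control hairpin (shNC) or a hairpin against ARID1A (shARID1A), per the labels' protocols. The cells were kept in medium without phenol red and with charcoal-stripped serum, which lowers steroid hormones, and then received DMSO, 10 nM estradiol (E2), or 10 nM E2 with 100 nM fulvestrant for 8 h. The fulvestrant dose is typed with letters in place of zeros in the labels and was read as 100 nM. The 12 libraries form 6 groups of 2, as the labels give them, and all 12 were used. The labels do not say whether the 2 libraries of a group came from separate cultures, nor how many hairpins or independent lines stand behind each arm. All p-values therefore measure spread between libraries, which may be technical, and an effect of ARID1A cannot be separated from any other difference between the shARID1A and shNC lines.

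The deposited values are counts, whole numbers of reads per gene, and the authors had applied no normalization to them. Reads had been trimmed with Trim Galore and cutadapt, checked with FastQC and aligned with Subread 2.0.0 to hg19, per the submitters' processing notes. Counting was done with featureCounts 2.0.0 over exons by gene, per the file headers, with no setting for strand, read pairs or reads with several alignments. Overlapping genes on opposite strands can therefore not be told apart, and genes with near-identical copies are reported as uncertain. Whether the reads were single or paired is not stated in the sources used here. The files for single libraries held 45320 genes, of which 14014 carry an Ensembl identifier as their name. The table for the series held 45293 of these genes, lacked 27 with symbols starting with SEP, MARC or DEC, and had 0 differing values for the genes in both. Totals ran from 28810351 to 38657162 counts per library and 20959 to 22076 genes had a count. A count of 3, taken as the floor for a gene with 0 counts, was 0.0776 to 0.104 CPM (counts scaled to a common library total), which covers counting error of single reads only.

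Counts were fitted in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr by group, which left 17020 genes, and library sizes were scaled by TMM factors. One model with a mean per group was fitted to all 12 libraries, because 2 libraries per group give few degrees of freedom alone. The 11 contrasts were tested with edgeR's quasi-likelihood F-test (glmQLFit with legacy = FALSE, then glmQLFTest), and adjusted p-values are Benjamini-Hochberg values over all genes within a contrast. A gene is called when its adjusted p is under 0.05. Contrasts were E2 against DMSO, E2 plus fulvestrant against E2 and E2 plus fulvestrant against DMSO within each arm, the difference between arms of the E2 effect and of the fulvestrant effect, and shARID1A against shNC within each treatment. Log2 fold changes are given with the standard error (SE) of the fit, and levels as CPM with the SD of the 2 libraries. DESeq2 1.42.0 was run beside edgeR.

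The contrasts, tests, gene lists and the rule for naming genes were fixed before the data were examined. Named genes are, for E2 in each arm, the difference of the E2 effect and the knockdown in DMSO, the 10 called genes with the largest increase and the 10 with the largest decrease. These needed a mean CPM of at least 1 in a compared group, both libraries of a group outside the range of the other group (for the difference, the same sign in all 4 combinations of libraries) and a gene symbol. For other contrasts the 5 largest each way were taken. ARID1A, ESR1, PGR and GREB1 and up to 4 members of each list with the smallest adjusted p were added in every contrast, called or not. Genes named outside this rule are marked as chosen after their values were seen.

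The 22 gene lists were estrogen response, nuclear receptors and coregulators, SWI/SNF subunits, cell cycle, p53 targets, epithelial, mesenchymal and matrix, interferon-stimulated, NF-kB and inflammatory, immediate early, YAP/TEAD targets, cholesterol synthesis, unfolded protein and amino acid response, hypoxia, amino acid and solute transporters, ribosome biogenesis, endometrial gland and secretory, stromal fibroblast, immune, endothelial, and neural and neuroendocrine markers, and mitochondrially encoded genes. They were written from general knowledge, and between 3 and 33 members of each passed the filter. Listed genes that did not match a symbol in the files, or that did not pass the filter, are not analysed here, and results for some single genes are not reported here. Lists were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01), adjusted over the 22 lists within a contrast. Camera with an estimated correlation and fry were run beside it.

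Power was tested on simulated data with changes of 1.25-, 1.5-, 2- and 4-fold placed in 50 genes per size. All 200 changed genes had a mean of at least 1 CPM and changed together, which eases the adjusted p threshold. For E2 in shNC, 60% of 1.5-fold and 84% of 2-fold changes were recovered. The shares were 44% and 66% for the difference of the E2 effect and 72% and 90% for the knockdown in DMSO. In these simulations 9, 10 and 11 unchanged genes were also called, respectively for E2 in shNC, the difference and the knockdown. Alternatives fixed beforehand were DESeq2 size factors, upper-quartile factors, the DESeq2 Wald test, no filter, a filter at 1 CPM in 2 libraries, fits with only the libraries compared, a replicate block, the legacy dispersion, a test against 1.5-fold, and leaving out each library. Alternatives added after the data were seen were removal of each library's trend with GC content (a GC value was available for 14953 genes, 87.9%), that correction with the replicate block, leaving out 2 libraries together, and thinning all libraries to the lowest total. Gene class and GC values were taken from GENCODE transcripts and gene order from RefSeq on GRCh38, while positions printed are those of the count files on hg19.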

Results

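RNA levels were measured by sequencing in Ishikawa cells, a line from a human endometrial adenocarcinoma. The cells carried either a control hairpin (shNC) or a hairpin against ARID1A (shARID1A), which encodes the large DNA-binding subunit of the SWI/SNF chromatin remodelling complex. Each arm was treated for 8 h with DMSO, 10 nM estradiol (E2), or 10 nM E2 with 100 nM fulvestrant, an antagonist that also promotes degradation of the estrogen receptor. This gave 6 groups of 2 libraries with 28810351 to 38657162 counts each, the deepest being replicate 2 of shARID1A with E2. In a principal component analysis of the 10338 genes with a mean of at least 5 CPM, the first component held 69.0% of the variance and separated the arms, and the second held 8.40%. Over 12461 genes with a mean count of at least 50, pairs of libraries from different arms differed 39.9 to 80.8 times more than counting error, measured as chi-square per degree of freedom. Pairs from the same arm with different treatments differed 4.71 to 16.7 times and replicate pairs 5.19 to 7.97 times. These multiples take each count as a separate read, and all would be lower, by up to a factor of 2, if both reads of a pair were counted.

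The comparison of shARID1A with shNC first checked the targeted gene. ARID1A (chromosome 1, 27055871 to 27107678, hg19) had 109.9 to 123.3 CPM in the 6 shNC libraries and 53.8 to 61.7 CPM in the 6 shARID1A libraries. Its log2 fold change was -0.96 in DMSO (SE 0.07, adjusted p = 7.6e-12), -1.11 with E2 (SE 0.07, adjusted p = 1.47e-13) and -1.03 with E2 plus fulvestrant (SE 0.07, adjusted p = 2.2e-12). About 50% of the transcript therefore remained at each treatment. ESR1, the gene for estrogen receptor alpha, had 2 to 34 counts per library, at most 1.08 CPM. PGR, the progesterone receptor gene and a classical estrogen target, had 0 counts in all 12 libraries, which at a floor of 3 counts allows up to 0.104 CPM, or double that if each read pair was counted as 2 reads. GREB1, another estrogen target, had 4.21 to 7.25 CPM and was not called in any of the 11 contrasts.

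**Figure D1:**
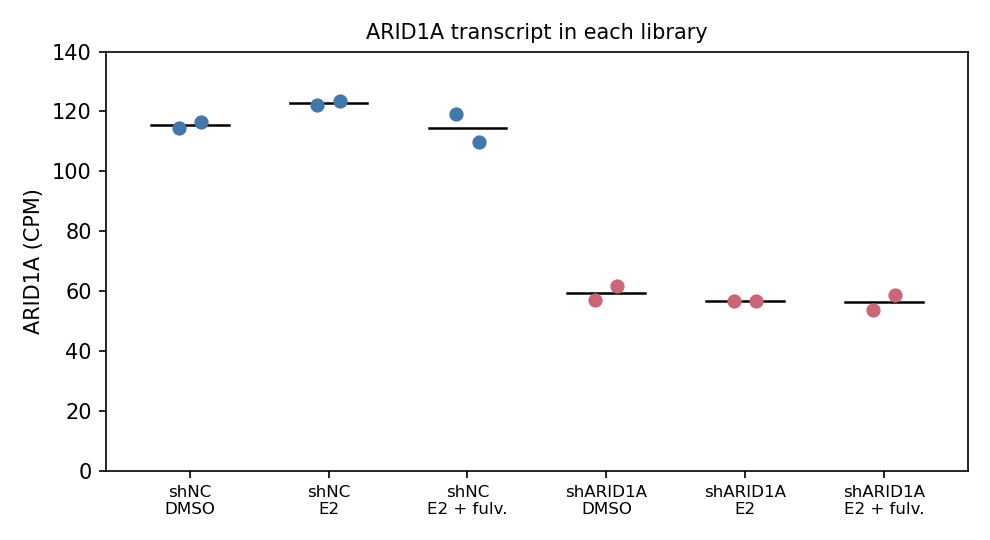
ARID1A in CPM for each of the 12 libraries, by arm and treatment, with horizontal bars at the mean of the 2 libraries of a group. The 6 shNC libraries lie at 109.9 to 123.3 CPM and the 6 shARID1A libraries at 53.8 to 61.7 CPM.

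The effect of the knockdown without hormone was read from shARID1A against shNC in DMSO. NR4A2, an orphan nuclear receptor and immediate early gene, rose from 14.1 ± 0.76 to 70.6 ± 0.75 CPM (SD, n = 2 each), a log2 fold change of 2.32 (SE 0.10, adjusted p = 3.99e-17). SCUBE1, which encodes a secreted and cell-surface protein with EGF-like repeats, rose from 1.52 to 17.7 CPM (log2 fold change 3.53, SE 0.24, adjusted p = 1.24e-12). The lipocalin gene LCN15 rose by 2.80 and the membrane dipeptidase gene DPEP1 by 2.45 on the log2 scale, and the axon guidance gene SEMA5A from 0.605 to 4.90 CPM. Among the genes that fell, TNC, which encodes the matrix protein tenascin-C, fell to 2.62 ± 0.36 CPM (log2 fold change -3.00, SE 0.17, adjusted p = 1.08e-14). The complement gene C3 fell from 4.15 to 0.384 CPM (log2 fold change -3.43, SE 0.39, adjusted p = 4.66e-08). EPS8L3, an EPS8-like adaptor, had the largest fitted decrease of the named genes, from 2.07 to 0.0836 CPM. That level lies under 3 counts, which were 0.0967 and 0.0985 CPM in these shARID1A libraries, so that the size of the fall is uncertain. The cytokine gene IL11 had a log2 fold change of -3.32, the proteoglycan gene DCN -3.58, the keratin gene KRT15 -3.63 and STRA6, which encodes a receptor for retinol-binding protein, -3.24. DCN, at 0.0829 CPM in shARID1A, was also under 3 counts. The other genes named by the rule were MRO, PTPRH, VIT and ARHGEF6, with increases of 2.31 to 2.77, and CNTD2, PLEK2 and FAM167A, with log2 fold changes of -3.14 to -3.79. The pseudogene GNG5P2 also rose, by 3.87 on the log2 scale, and is described with the E2 comparison, since reads from gene copies are uncertain.

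In DMSO 1651 genes were higher and 1617 lower in shARID1A of 17020 tested. Changes were mostly small, with 2155 of the 3268 called genes under 1.5-fold, 152 higher by over 2-fold and 379 lower by over 2-fold. DESeq2 called 1747 higher and 1550 lower. The count was 2065 without replicate 2 of shNC in DMSO and 2026 without replicate 2 of shARID1A in DMSO. Tested against a change of 1.5-fold, 308 genes passed.

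The same genes were then compared in the presence of E2 and of E2 plus fulvestrant. FBN2, which encodes the microfibril protein fibrillin-2, fell from 290.2 ± 9.32 CPM in shNC to 53.6 ± 3.03 CPM in shARID1A (SD over the 6 libraries of each arm), with log2 fold changes of -2.46, -2.45 and -2.41 in DMSO, E2 and E2 plus fulvestrant. CASP9, which encodes the initiator caspase of the mitochondrial apoptosis pathway, rose from 33.0 ± 2.23 CPM in shNC by 2.06, 2.07 and 2.14 on the log2 scale. TBXA2R, the thromboxane A2 receptor gene, rose by 1.95, 1.91 and 1.97 on the log2 scale. SULF2, which encodes an extracellular heparan sulfate endosulfatase, had log2 fold changes of -2.18, -2.13 and -2.23. NR4A2 rose by 2.32 with E2 and 2.39 with E2 plus fulvestrant. FBN2, CASP9, TBXA2R and SULF2 were chosen after their values were seen, from the genes with the largest changes in all 3 treatments.

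**Figure D2:**
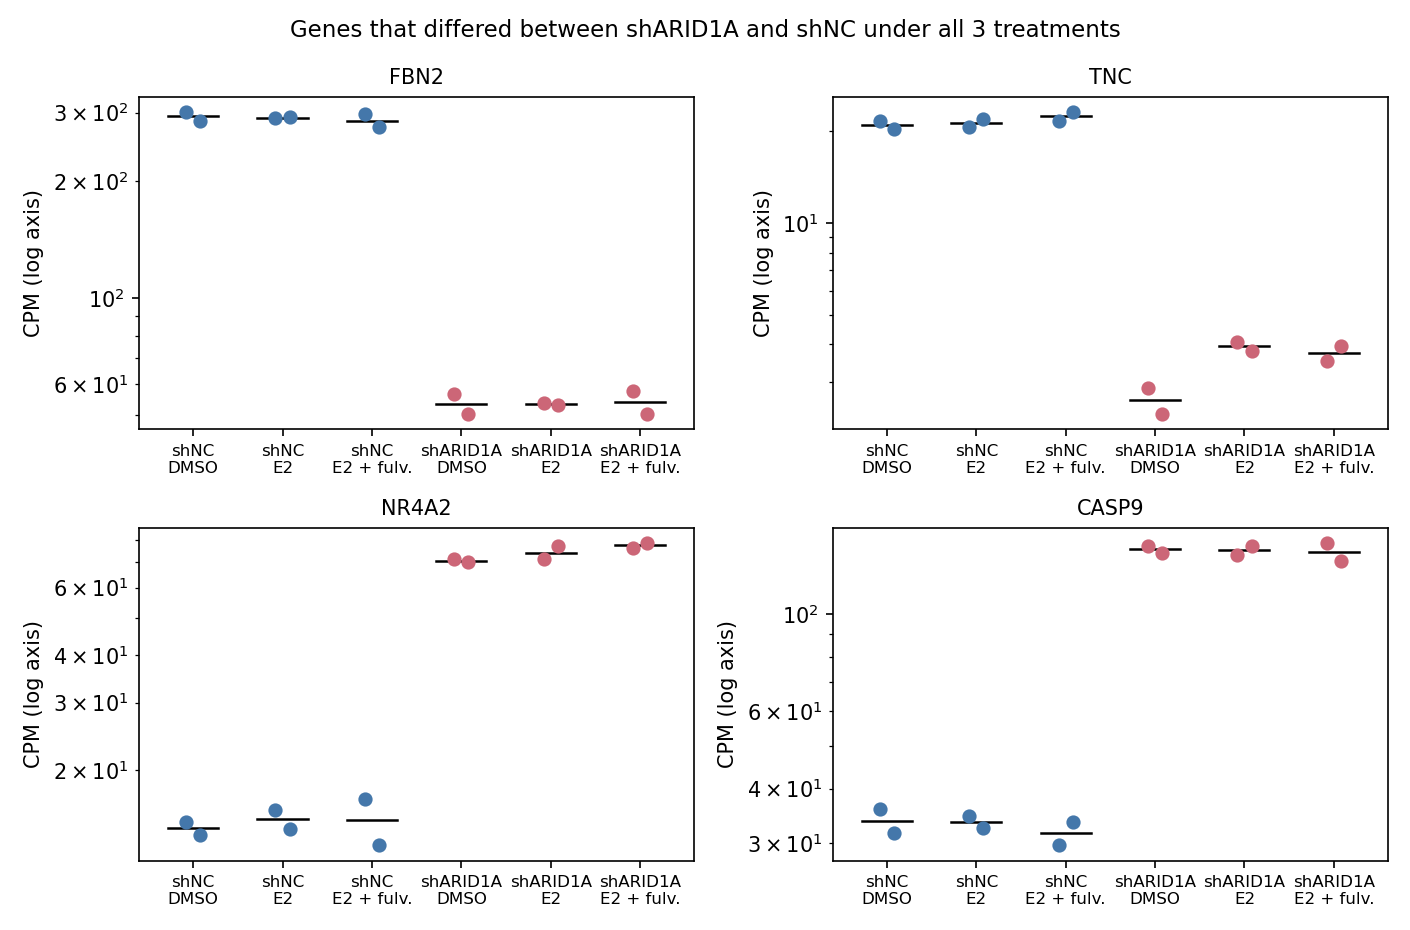
FBN2, TNC, NR4A2 and CASP9 in CPM on a log axis for each of the 12 libraries, by arm and treatment. In each panel the 6 shNC and the 6 shARID1A libraries do not overlap, with NR4A2 and CASP9 higher and FBN2 and TNC lower in shARID1A.

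With E2, 2279 genes were higher and 2354 lower in shARID1A, led by SHOX2 (log2 fold change 3.67), MRO (3.57), SCUBE1 (3.19), ADAMTS7 (3.12) and LCN15 (3.02), and by STRA6 (-4.59), FAM167A (-4.11), ZNF365 (-3.73), EPS8L3 (-3.56) and CXXC4 (-3.47). With E2 plus fulvestrant, 1943 were higher and 2177 lower. GNG5P2 (5.59), the deiodinase gene DIO3 (4.38), MYCL (3.90), MRO (3.63) and DPEP1 (3.54) led the increases. MYCL was not called by DESeq2, with an adjusted p of 0.0922. STRA6 had 0 counts in both shARID1A libraries with E2 plus fulvestrant. FAM167A (-3.90), DCLK1 (-3.49), CNTD2 (-3.35) and ABLIM3 (-3.31) followed among the decreases. DESeq2 called 2219 higher and 2126 lower with E2, and 2174 and 1962 with E2 plus fulvestrant. The same direction was called in all 3 treatments for 1151 higher and 1107 lower genes, of 6060 called in at least 1, and 3 genes were called in opposite directions in some pair. DMSO and E2 shared 1328 higher genes, where independent lists (n1 × n2 / N) would share 221, and 1240 lower genes against 224. DMSO and E2 plus fulvestrant shared 1255 and 1216, against 189 and 207, and E2 and E2 plus fulvestrant shared 1542 and 1635, against 260 and 301. Across the 10338 genes with a mean of at least 5 CPM, the knockdown log2 fold changes of 2 treatments correlated at 0.860 to 0.903, and genes are not independent replicates. Over all 17020 tested genes, which include those with few counts, the correlations were 0.478 to 0.496. The E2 count was 2770 without replicate 2 of shNC with E2 and 2813 without replicate 2 of shARID1A with E2. The count with E2 plus fulvestrant was 2604 without replicate 2 of that group in shNC and 2336 without replicate 1 of that group in shARID1A.

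Most of the mesenchymal and matrix genes that were called were lower in shARID1A. Of the 21 measured members of the mesenchymal and matrix list, 12 were lower and 2 higher in DMSO, 12 and 3 with E2, and 11 and 3 with E2 plus fulvestrant. TGFBI, a TGF-beta-induced matrix protein gene, had log2 fold changes of -1.67, -1.63 and -1.72, the N-cadherin gene CDH2 -1.36, -1.51 and -1.43, and the integrin alpha-5 gene ITGA5 -0.95, -0.92 and -0.93. The fibronectin gene FN1, chosen after its values were seen, fell from 7.25 ± 0.64 to 1.04 ± 0.17 CPM (SD, 6 libraries of each arm). The basement membrane collagen genes COL4A1 and COL4A2, also chosen after their values were seen, rose, by 0.44 and 0.37 in DMSO. The list was called lower by camera in each treatment, with adjusted p = 1.11e-13, 4.66e-14 and 4.95e-15, and remained called with an estimated correlation (adjusted p = 0.00303, 0.00281 and 0.00232). Adjusted over the list alone, 12 members were lower and 5 higher in DMSO, 12 and 3 with E2, and 13 and 3 with E2 plus fulvestrant.

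**Figure D3:**
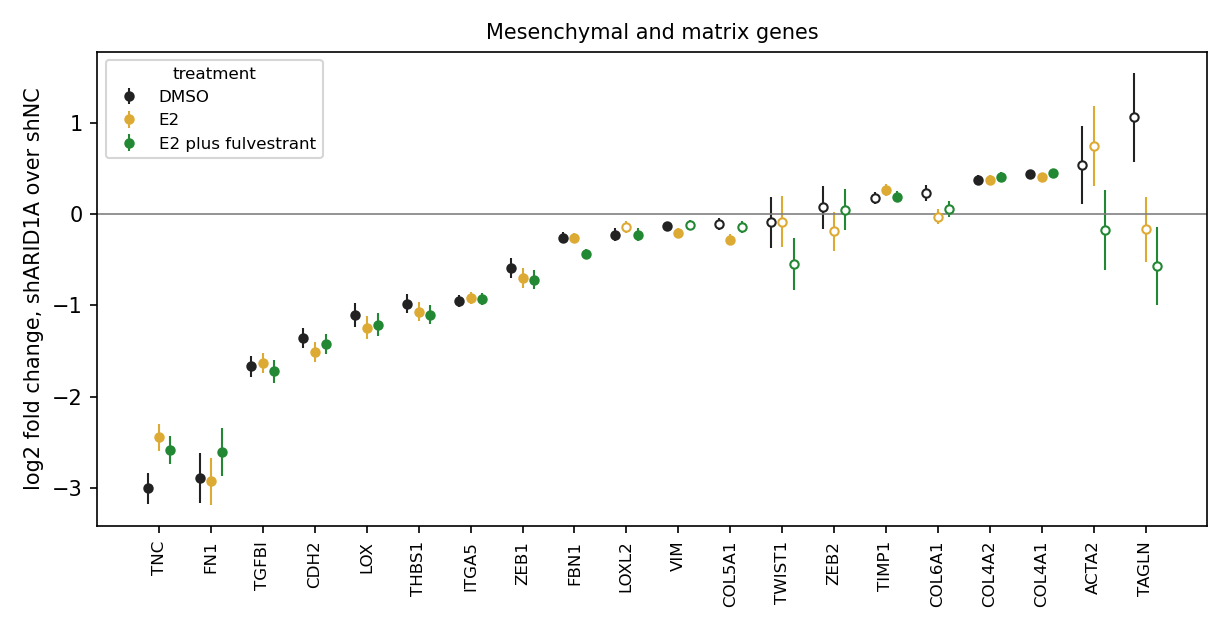
Log2 fold change of shARID1A against shNC for 20 of the 21 measured members of the mesenchymal and matrix list in each of the 3 treatments, with bars of 1 standard error and filled points for adjusted p under 0.05. Of those shown, TNC, FN1 and TGFBI lie lowest, and COL4A1 and COL4A2 are called higher.

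Of the 20 measured members of the unfolded protein and amino acid response list, 11 were called lower in shARID1A and 2 higher in DMSO, 13 and 2 with E2, and 14 and 1 with E2 plus fulvestrant. In DMSO the endoplasmic reticulum chaperone gene HYOU1 had a log2 fold change of -0.58, the stress-induced pseudokinase gene TRIB3 -0.65, the mitochondrial folate enzyme gene MTHFD2 -0.47 and the cystine transporter gene SLC7A11 -1.13. Camera called the list lower with adjusted p = 8.49e-06, 0.000339 and 5.57e-06, and with an estimated correlation the adjusted p was 0.0438, 0.0906 and 0.0379, so that the call with E2 was lost. With p adjusted over the list alone, 14, 14 and 15 members were lower and 2, 3 and 1 higher.

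Mitochondrially encoded genes, which encode subunits of the respiratory chain and ATP synthase, were mostly higher in shARID1A. Of 13, 11, 10 and 11 were called higher and 0 lower in DMSO, E2 and E2 plus fulvestrant by edgeR, with MT-CYB up by 0.43, 0.44 and 0.44 and MT-CO1 by 0.32, 0.33 and 0.32. All genes with a symbol starting with MT-, without limit to the 13 listed, made up 4.91 ± 0.14% of counts in shNC and 5.62 ± 0.08% in shARID1A (SD, n = 6 each). A two-sided exact permutation test of the 12 libraries, without regard to treatment, gave p = 0.00216, the smallest value that test can give. Camera called the list higher with adjusted p = 7.59e-06, 1.06e-06 and 8.51e-09, and the call was lost in each treatment with an estimated correlation (adjusted p = 0.203, 0.211 and 0.183). When p was adjusted over the list alone, 11, 12 and 11 members were higher and 0 lower.

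Of 17 members of the NF-kB and inflammatory list, 8, 11 and 9 were called lower in shARID1A in DMSO, E2 and E2 plus fulvestrant, and 1 was called higher in each treatment. The cytokine gene IL32 had log2 fold changes of -0.98, -0.79 and -1.01, and the mitochondrial superoxide dismutase gene SOD2 -0.42, -0.35 and -0.42. RELB, an NF-kB subunit gene, had -0.53 in DMSO. NFKBIA, which encodes an inhibitor of NF-kB, was the member that rose, by 0.37, 0.52 and 0.32. Camera called the list lower (adjusted p = 0.000143, 0.00132 and 0.00225), and the call was lost with an estimated correlation (adjusted p = 0.172, 0.211 and 0.205). Adjusted over the list alone, 10, 11 and 10 members were lower and 2, 1 and 2 higher.

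Immediate early genes went both ways, with 5 of 15 higher in each treatment and 3, 4 and 3 lower. NR4A2, KLF4 (0.82 in DMSO), NR4A1 (0.75) and FOSL2 (0.49), all transcription factor genes, rose, while FOSL1 (-0.75) fell. Camera called the list higher (adjusted p = 0.000726, 0.00647 and 0.00669), which was lost with an estimated correlation (adjusted p = 0.0509, 0.0916 and 0.0988) and with no filter on low counts (adjusted p = 0.0833, 0.192 and 0.376). With E2 plus fulvestrant the list's median was -0.13 while its mean was 0.01 and the test pointed up. With p adjusted over the list alone, 6, 5 and 5 members were higher and 3, 4 and 4 lower. Among YAP/TEAD targets, which respond to the Hippo pathway, 7, 10 and 8 of 18 were higher and 2, 3 and 2 lower. AMOTL1, an angiomotin gene, rose by 0.70, 0.70 and 0.78, ARHGEF17 by 0.72, 0.69 and 0.62, and CYR61, a secreted matricellular protein gene, by 0.58, 0.43 and 0.53. Camera called this list higher (adjusted p = 0.00441, 0.00483 and 0.00669), lost with an estimated correlation (adjusted p = 0.0703, 0.0906 and 0.0988). When p was adjusted over the list alone, 7, 10 and 9 YAP/TEAD targets were higher and 4, 3 and 3 lower.

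Of 16 p53 targets, 6, 7 and 7 were lower and 2, 1 and 1 higher in shARID1A. CDKN1A, which encodes the cell-cycle inhibitor p21, had log2 fold changes of -0.70, -0.66 and -0.82, and GDF15, a stress-induced cytokine gene, -1.01, -1.10 and -1.17. AEN, an apoptosis-related nuclease gene, rose by 0.36 in DMSO. Camera called the list lower (adjusted p = 0.0209, 0.0176 and 0.00669), lost with an estimated correlation (adjusted p = 0.203, 0.229 and 0.198). Leaving out replicate 1 of shNC or of shARID1A in DMSO gave adjusted p = 0.0783 and 0.109 there, and leaving out replicate 1 of shNC with E2 gave 0.0725 there. Adjusted over the list alone, 7, 8 and 7 were lower and 2, 1 and 1 higher.

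Hypoxia genes and cholesterol synthesis genes were called higher in shARID1A with E2. For hypoxia, 9 of 24 were higher and 3 lower with E2, against 4 and 5 in DMSO and 4 and 2 with E2 plus fulvestrant. The glucose transporter gene SLC2A3 rose by 1.07, 1.11 and 1.01 and NDRG1, a stress-responsive gene, by 0.69, 1.00 and 0.86 across treatments. The hypoxia list had adjusted p = 0.0135 with E2 by camera, 0.22 in DMSO and 0.176 with E2 plus fulvestrant, and with E2 the adjusted p = 0.552 with an estimated correlation and 0.066 by fry. It had adjusted p = 0.0725 with E2 without replicate 1 of shNC and 0.247 without replicate 2 of shARID1A. With p adjusted over the list alone, 11 were higher and 3 lower with E2, 7 and 6 in DMSO, and 4 and 2 with E2 plus fulvestrant. Of 23 cholesterol synthesis genes, 8, 10 and 8 were higher and 3, 2 and 3 lower in DMSO, E2 and E2 plus fulvestrant. ACAT2 (0.43 in DMSO), which encodes an enzyme that makes acetoacetyl-CoA, rose, and INSIG1 (-0.65), which restrains cholesterol synthesis, fell. This list had adjusted p = 0.0337 with E2, 0.0808 in DMSO and 0.252 with E2 plus fulvestrant, and with E2 the adjusted p = 0.324 with an estimated correlation. Its value with E2 was 0.0725 without replicate 1 of shNC with E2, and 0.0503 or 0.0501 without replicate 1 or 2 of shNC with E2 plus fulvestrant. When p was adjusted over the list alone, 10, 10 and 8 were higher and 3, 2 and 3 lower. The difference of the E2 effect between arms did not pass for either list (adjusted p = 0.134 for hypoxia and 0.899 for cholesterol synthesis).

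Estrogen response genes went both ways in shARID1A and the list was not called by camera or fry. In DMSO 8 of 33 members were higher and 7 lower, in E2 9 and 5, and in E2 plus fulvestrant 10 and 3. The insulin-like growth factor binding protein gene IGFBP4 rose by 0.62 and the placental alkaline phosphatase gene ALPP by 0.85 in DMSO, while the carbonic anhydrase gene CA12 had -1.24 and IER3, a stress-response gene, -0.99. Camera gave adjusted p = 0.825, 0.576 and 0.432, and in DMSO the median of -0.01 and mean of -0.13 were negative while the test pointed up. With E2 plus fulvestrant the median of -0.03 and mean of -0.04 were again negative with the test pointing up, and with E2 the median was 0.02 and the mean -0.02. Adjusted over the list alone, 9, 10 and 10 were higher and 9, 5 and 3 lower. Of 20 nuclear receptors and coregulators, 5 were higher and 1 lower in DMSO (adjusted p = 0.362), with TFAP2A, a transcription factor gene, up by 0.70. Of 26 other SWI/SNF subunits, 3 were higher and 2 lower in DMSO (adjusted p = 0.747), among them PHF10 (0.52) and the ATPase gene SMARCA4 (0.27). With p adjusted over the list alone, 5 nuclear receptors and coregulators were higher and 2 lower, and 4 SWI/SNF subunits were higher and 2 lower. Medians and test differed in sign for SWI/SNF subunits (median -0.00, mean 0.01, test up) and, in the mean, for nuclear receptors (median 0.03, mean -0.06, test up).

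The remaining lists were not called by camera between the arms in DMSO, E2 or E2 plus fulvestrant, and their values in DMSO follow. Fry, which asks whether the members of a list moved in 1 direction and not whether they moved more than other genes, called 15, 14 and 13 of the 22 lists in these contrasts against 7, 9 and 7 by camera. In DMSO fry called transporters (adjusted p = 0.00026), endometrial gland (0.000833), epithelial (0.00938) and cell cycle genes (0.014) lower. It called interferon-stimulated (0.00307), cholesterol synthesis (0.014), nuclear receptor (0.0262) and neural genes (0.0368) higher. With E2 it called transporters (0.000385), endometrial gland (0.000643), epithelial (0.0152) and cell cycle genes (0.0366) lower and interferon-stimulated (0.0366) and neural genes (0.045) higher. With E2 plus fulvestrant transporters (0.000137), endometrial gland (0.000907), immune (0.0107), epithelial (0.0168) and cell cycle genes (0.0264) were lower and neural genes (0.0291) higher by fry. Of the lists called by camera between the arms, fry did not call hypoxia with E2. The arms also differed in measures of whole libraries, which may be technical or part of the expression difference itself. The deviation of the lowest-GC genes was -0.026 to 0.205 in shNC and -0.201 to 0.018 in shARID1A. The share of counts in the 10 most abundant genes was 6.6 to 6.84% and 7.3 to 7.53%. Such differences move together with the knockdown, and GC correction left all camera list calls between the arms in place. For the cell cycle list, 4 of 33 members were higher and 9 lower (adjusted p = 0.387), with the cyclin gene CCNB2 at -0.35, the kinase gene AURKA at -0.33, and the replication helicase gene MCM5 up by 0.24, which was not called without replicate 2 of shNC in DMSO (0.20). Of 17 epithelial genes, 3 were higher and 5 lower (adjusted p = 0.0808), with the simple-epithelium keratin genes KRT8 at -0.75 and KRT18 at -0.55 and the plakophilin gene PKP3 up by 0.51. Interferon-stimulated genes had 3 of 18 higher and 0 lower by edgeR (adjusted p = 0.208), led by OAS1, an antiviral enzyme gene, at 0.90. Amino acid and solute transporters had 2 of 17 higher and 5 lower (adjusted p = 0.107), with the amino acid transporter gene SLC43A2 at -2.11. For ribosome biogenesis, 2 of 24 were higher and 2 lower (adjusted p = 0.958), and the polymerase I subunit gene POLR1A rose by 0.29. Of 11 endometrial gland and secretory genes, 1 was higher and 4 lower (adjusted p = 0.0808), with the cell-surface receptor gene CD44 at -0.78 and LGR4, a receptor for R-spondins, up by 0.75. Markers of other cell types were few after the filter. Stromal fibroblast markers had 1 of 3 higher and 1 lower (adjusted p = 0.747), namely COL1A1 at 0.50 and DCN at -3.58. Immune markers had 1 of 3 higher (adjusted p of the list 0.825), endothelial markers 1 of 3 higher (EGFL7, adjusted p of the list 0.558) and neural markers 1 of 4 higher (SNAP25, adjusted p of the list 0.362), and 0 of these were lower by edgeR. SNAP25 was not called without replicate 2 of shARID1A in DMSO (0.64, from 0.75). When p was adjusted over the list alone, the higher and lower counts were 4 and 10 for cell cycle, 3 and 7 for epithelial, 4 and 0 for interferon-stimulated, 2 and 5 for transporters, 2 and 2 for ribosome biogenesis, 1 and 6 for endometrial gland, 1 and 2 for stromal, 1 and 0 for immune, 1 and 1 for endothelial and 1 and 0 for neural genes. For immune markers the median of -0.03 and mean of -0.18 were negative while the test pointed up.

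The response of control cells to hormone was read from E2 against DMSO in shNC. GNG5P2, a pseudogene of the G-protein subunit gene GNG5 (X chromosome, 109589700 to 109590201), rose from 0.212 and 0.135 CPM to 3.70 and 4.58 CPM, a log2 fold change of 4.54 (SE 0.54, adjusted p = 2.41e-05). GREB1 had a log2 fold change of 0.44 (SE 0.19, adjusted p = 1), ESR1 0.06, and NDRG1 -0.36 (SE 0.08, adjusted p = 0.263). By edgeR 1 gene was higher and 0 lower, with 656 genes at an unadjusted p under 0.05, where 851 would be expected by chance, and DESeq2 called the same numbers of 1 and 0. Of 50 listed estrogen response genes 43 matched a symbol in the files and 33 were tested, so that several classical estrogen targets are not analysed here. By edgeR 0 of the 33 were called, also adjusted over the list alone, and the list had adjusted p = 0.902 (median -0.01, mean -0.02, test up). The hypoxia list was called lower by camera (adjusted p = 8.05e-08), with 0 members called over all genes, 0 higher and 2 lower adjusted over the list alone, and adjusted p = 0.484 with an estimated correlation and 0.412 by fry. In simulated data this contrast recovered 60% of 1.5-fold changes and 32% of the smallest changes placed. The count was 4 without replicate 1 of shNC in DMSO or without replicate 2 of shNC with E2, and 2 without replicate 1 of shNC with E2.

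In shARID1A, E2 against DMSO called 3 genes higher and 1 lower. RPL37, a large-subunit ribosomal protein gene (chromosome 5, 40827805 to 40835314), rose by 0.33 (SE 0.06, adjusted p = 0.0368). The ferritin pseudogene FTH1P20 rose by 0.30 (SE 0.06, adjusted p = 0.0468), and RP11-543P15.1, a locus outside the naming rule that was added after its values were seen, by 0.37 (SE 0.07, adjusted p = 0.0397). EIF5AP4, a pseudogene of a translation factor gene, fell by 1.32 on the log2 scale (SE 0.21, adjusted p = 0.00978). At an unadjusted p under 0.05 there were 1125 genes, and DESeq2 called 5 higher and 1 lower. The estrogen response list was not called by camera (adjusted p = 0.629) or fry. The count was 0 without replicate 2 of shARID1A in DMSO or with E2, 2 without replicate 1 of shARID1A with E2, and 1 without either library of shNC with E2 plus fulvestrant. RPL37 and FTH1P20 were not called in this arm without any 1 of these libraries or replicate 1 of shARID1A in DMSO, with adjusted p of 0.0679 to 0.65 for RPL37 and 0.0906 to 0.879 for FTH1P20. EIF5AP4 was not called without replicate 2 of shARID1A in DMSO (log2 fold change -1.09, adjusted p = 0.65) or with E2 (-1.11, adjusted p = 0.614).

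The test of whether the knockdown changed the E2 response was the difference of both E2 effects. RPL37 had a difference of 0.53 (SE 0.09, adjusted p = 0.00262), FTH1P20 of 0.53 (SE 0.08, adjusted p = 0.00216), RP11-543P15.1 of 0.64 (SE 0.10, adjusted p = 0.00216) and MT-ND3, a mitochondrially encoded subunit of complex I, of 0.45 (SE 0.08, adjusted p = 0.0112). GNG5P2 had a difference of -4.38 (SE 0.69, adjusted p = 0.00216), with 3.11 and 2.12 CPM in DMSO and 1.73 and 3.95 CPM with E2 in shARID1A. By edgeR 4 genes were higher and 1 lower, with 1079 at an unadjusted p under 0.05, and DESeq2 called 15 higher and 0 lower. The count of 5 became 12 with a replicate block, 23 with GC correction, 30 with both, 19 with only the libraries compared and 41 with no filter on low counts. Between the arms 0 of the 1 and 4 genes called with E2 by edgeR were shared, where n1 × n2 / N is 0.000235 (two-sided Fisher exact p = 1). The gene called in shNC had a log2 fold change of 0.16 in shARID1A (0.59 and -0.60 without replicate 1 and 2 of that arm with E2), and the median in shNC of those called in shARID1A was -0.21, with an orthogonal slope of 0.05 over the 5 genes. The count was 8 without replicate 1 of shNC in DMSO, 16 without replicate 1 of shNC with E2, 3 without replicate 1 of shARID1A in DMSO, and 18 without either library of shARID1A with E2 plus fulvestrant. Without replicate 1 of shARID1A in DMSO, GNG5P2 (-4.08) and RPL37 (0.51) had adjusted p = 0.0627. MT-ND3 was not called in 5 of the 12 fits without a library, those without replicate 2 of shNC in DMSO or with E2, either shARID1A library in DMSO, or replicate 1 of shARID1A with E2 (adjusted p = 0.0907, 0.193, 0.136, 0.071 and 0.132). The gene called by E2 in shNC, GNG5P2, was higher in shARID1A with E2 plus fulvestrant, by 5.59, at percentile 100 of 10000 draws from the genes within 100 ranks of it in mean expression. Each draw was 1 gene, so that the percentile only ranks GNG5P2 among these neighbours. In DMSO GNG5P2 was higher by 3.87, but the shNC libraries in DMSO also entered the contrast that selected it, so that random genes give no reference there. The value with E2 plus fulvestrant became 2.87 without replicate 1 of shNC in DMSO and 2.48 without replicate 2 of shNC with E2, each a median over the 2 genes called higher there. Without replicate 1 of shNC with E2 plus fulvestrant the remaining library had 0 counts, and the fitted value of 10.2 is no bound.

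**Figure D4:**
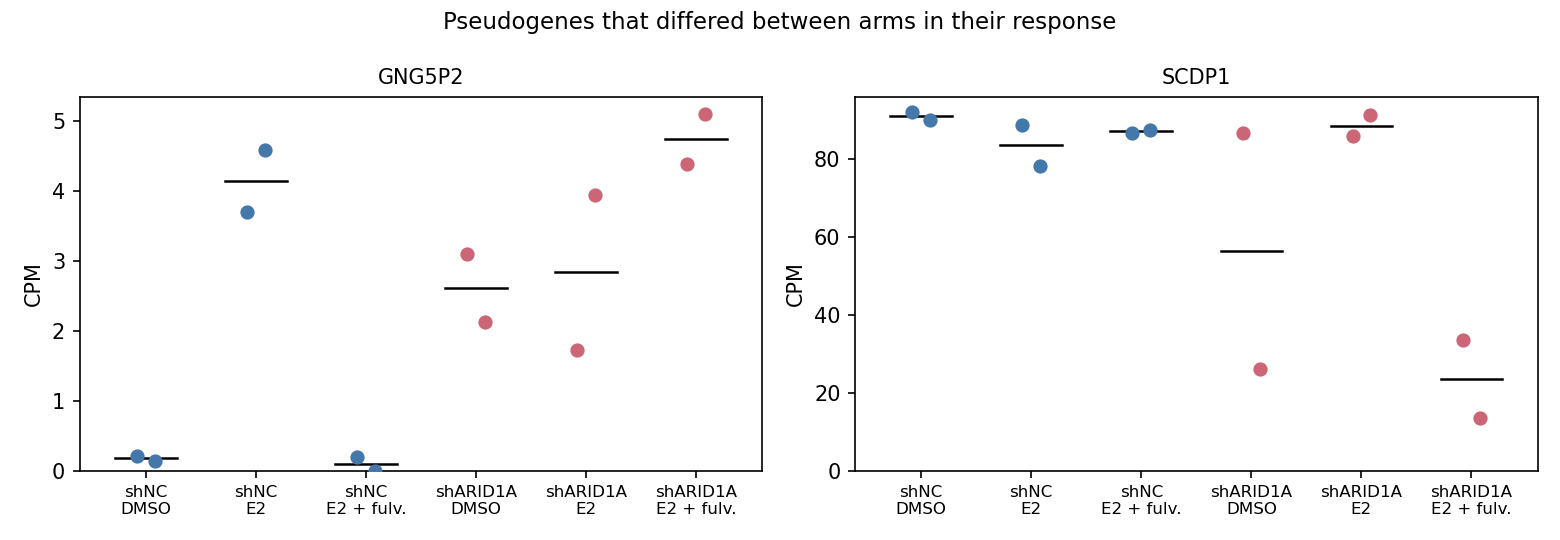
GNG5P2 and SCDP1, pseudogenes whose response differed between the arms, in CPM for each of the 12 libraries, by arm and treatment. GNG5P2 is near 0 CPM in shNC except with E2 (3.70 and 4.58 CPM), and SCDP1 is at 78.2 to 92.0 CPM in shNC and between 13.4 and 91.1 CPM in shARID1A.

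Addition of fulvestrant to E2 asked what depended on the receptor, although without a group given fulvestrant alone its own effects are not separated. In shNC GNG5P2 fell, to 0.188 and 0 CPM (log2 fold change -5.40, SE 0.61, adjusted p = 7.83e-06), so that the 1 gene called with E2 was reversed by edgeR. The shNC libraries with E2 entered both contrasts. DESeq2 gave GNG5P2 a log2 fold change of -5.46 but no adjusted p here, and so did not call it. In shARID1A the pseudogene SCDP1 (chromosome 17, 20687958 to 20689038) fell from 85.8 and 91.1 to 33.6 and 13.4 CPM (log2 fold change -1.92, SE 0.27, adjusted p = 0.0013), but its libraries in DMSO had 86.6 and 26.0 CPM and DESeq2 did not call it (adjusted p = 0.134). TRIB3 had -0.33 in shARID1A (adjusted p = 0.133 by edgeR and 0.0199 by DESeq2). By edgeR 0 genes were higher and 1 lower in each arm, with 1324 and 1665 genes at an unadjusted p under 0.05 in shNC and shARID1A. DESeq2 called 0 higher and 2 lower in shNC and 6 and 7 in shARID1A. None of the 4 genes called with E2 in shARID1A was called in the opposite direction by edgeR. The number reversed over both arms, 1, was 2 without replicate 2 of shNC with E2, replicate 1 of shARID1A in DMSO or replicate 1 of shARID1A with E2, and 3 without replicate 1 of shARID1A with E2 plus fulvestrant. At an unadjusted p under 0.05, fulvestrant reversed 125 of 656 E2 genes in shNC (19.1%), where 20 simulations without any effect gave 16.1 to 21.6%, and 412 of 1125 in shARID1A (36.6%), where they gave at most 20%. Replicate 2 of shARID1A with E2, which enters both contrasts, had the lowest level of genes of low GC content of all 12 libraries (-0.20 on the log2 scale for the 20% of genes lowest in GC). The simulations drew each gene separately, without such a trend, and gave a mean of 864 genes at an unadjusted p under 0.05 in shARID1A. Their share is therefore no full reference for the 36.6%. SCDP1 in shARID1A had adjusted p = 0.127 without replicate 2 of that arm with E2 plus fulvestrant, and the count in shARID1A was 27 without replicate 1 of that group and 2 without either shARID1A library with E2. In shNC the count was 2 without either library in DMSO, 3 and 6 without replicate 1 and 2 with E2, and 5 without replicate 2 with E2 plus fulvestrant.

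Gene lists moved little with fulvestrant. In shNC camera called NF-kB genes lower (adjusted p = 0.0438), hypoxia genes higher (0.0438) and mitochondrially encoded genes lower (0.0124), with 0 members of each called by edgeR over all genes. Adjusted over the list alone, these had 0, 1 and 0 members higher and 0, 0 and 1 lower, and each list had adjusted p = 0.833 with an estimated correlation and 0.514, 0.555 and 0.514 by fry. The same shNC libraries with E2 entered this contrast, E2 against DMSO in shNC, and shARID1A against shNC with E2. The hypoxia calls in these contrasts are therefore not independent, and do not show an E2 effect reversed by fulvestrant. In shARID1A cholesterol synthesis and unfolded protein genes were called lower by camera (adjusted p = 0.033 each), with 0 members called by edgeR over all genes. DESeq2 called TRIB3 of the unfolded protein list lower (adjusted p = 0.0199). Adjusted over the list alone, 0 and 1 members were lower by edgeR, and the lists had adjusted p = 0.597 with an estimated correlation and 0.174 and 0.168 by fry. The NF-kB call was lost with the replicate block (adjusted p = 0.0633), with GC correction (0.171), with both (0.228) and with no filter on low counts (0.183), in all under 10 of 20 settings, and the hypoxia call was lost under 7, with no filter at 0.0513. Without replicate 1 of shNC with E2, NF-kB and hypoxia genes had adjusted p = 0.66. Without replicate 1 or 2 of shNC with E2 plus fulvestrant, NF-kB genes had 0.142 and 0.208, hypoxia genes 0.0748 and 0.387, and mitochondrially encoded genes 0.285 without replicate 1, a call lost under 3 of 20 settings. Cholesterol synthesis and unfolded protein genes in shARID1A lost their call under 13 of 20 settings each, with DESeq2 size factors at 0.0512. They were not called without any 1 of the 6 shNC libraries (0.0615 to 0.0879) or either shARID1A library with E2 (0.0707 to 0.127). They had adjusted p = 0.659 without replicate 2 and 0.518 without replicate 1 of shARID1A with E2 plus fulvestrant, respectively. The fulvestrant effect differed between the arms for GNG5P2 (6.09, SE 0.69, adjusted p = 8.75e-06) and SCDP1 (-1.98, SE 0.36, adjusted p = 0.0398), 1 gene higher and 1 lower, with 592 at an unadjusted p under 0.05. DESeq2 called 1 higher and 0 lower. The number was 4 without replicate 2 of shNC with E2, 1 without replicate 1 of shNC with E2 plus fulvestrant and 5 without replicate 1 of shARID1A with E2 plus fulvestrant. In 5 of the 12 fits without a library SCDP1 was not called (adjusted p = 0.141 to 0.611), those without any 1 of the shNC libraries with E2 plus fulvestrant, the shARID1A libraries with E2, or replicate 2 of shARID1A with E2 plus fulvestrant.

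E2 plus fulvestrant was also compared with DMSO. No group received fulvestrant alone, so that what remained of the E2 effect cannot be separated from an effect of fulvestrant itself. In shNC MRPL17, a mitochondrial ribosomal protein gene (chromosome 11, 6702382 to 6704547), had a log2 fold change of -0.44 (SE 0.07, adjusted p = 0.0178) and MT-ND5, a complex I subunit gene, of -0.24 (SE 0.04, adjusted p = 0.0178). By edgeR 0 genes were higher and 2 lower in shNC, with 1615 at an unadjusted p under 0.05, and DESeq2 called 2 higher and 11 lower. In shARID1A 0 genes were called by edgeR and 0 by DESeq2, with 695 and 609 at an unadjusted p under 0.05. Mitochondrially encoded genes were called lower in shNC by camera (adjusted p = 0.000478), with adjusted p = 0.767 with an estimated correlation and 0.408 by fry. By edgeR 1 member was lower over all genes and 4 were lower adjusted over the list alone. Besides MT-ND5, DESeq2 called MT-ND6 (adjusted p = 0.000792), MT-ND3 and MT-ND1 (0.0127 each) lower over all genes. Without replicate 2 of shNC in DMSO that list had adjusted p = 0.21, and without replicate 1 of shNC with E2 plus fulvestrant 0.278. In shARID1A the 3 immune markers were called lower (adjusted p = 0.0265, 0 members called, adjusted p = 0.374 with an estimated correlation), all at low counts, with 0.0115 by fry and 0.604 with no filter, lost under 4 of 20 settings, and without replicate 1 in DMSO or replicate 2 with E2 plus fulvestrant the list had adjusted p = 0.119 and 0.253. MRPL17 was not called without replicate 1 of shNC in DMSO (adjusted p = 0.188) or replicate 2 of shNC with E2 plus fulvestrant (0.121), and neither it nor MT-ND5 without replicate 1 of shNC with E2 plus fulvestrant (0.433) or replicate 1 or 2 of shARID1A in DMSO (0.0542 and 0.0524). The count in shNC was 4 and 6 without replicate 1 and 2 in DMSO, 7 without either shNC library with E2, 0 and 10 without replicate 1 and 2 with E2 plus fulvestrant, and 0 without either shARID1A library in DMSO. In shARID1A it was 4 and 1 without replicate 1 and 2 in DMSO and 4 without replicate 1 with E2 plus fulvestrant.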

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

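In this part the tests of GC content on the differing genes and on the ratio of knockdown counts, of small changes called in DMSO and of the ESR1 level were chosen after the results were seen. For mixed-up labels, larger knockdown effects and shared reads, the predictions were written before, but the rules that read the outcome were tightened after the values were seen.

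In 7 cases the effect of E2 or of fulvestrant differed between shARID1A and shNC by the test of the difference itself. For the E2 effect these were FTH1P20 (0.527), RPL37 (0.53), RP11-543P15.1 (0.635), GNG5P2 (-4.377) and MT-ND3 (0.451), and for the fulvestrant effect GNG5P2 (6.093) and SCDP1 (-1.983). A GC trend between libraries as the whole cause was argued against for 6 effects, of which 6 remained called in the same direction after its removal (0.513, 0.582, -4.401, 0.542, 6.103 and -1.976), while RP11-543P15.1 had no GC value, was left at 0.635 and stays open. Reads shared between gene copies may still contribute: over 1286 pseudogenes and 10985 protein-coding genes, variance between replicates relative to the mean was 0.891 (0.853 to 0.930) times as large in pseudogenes, which met the bound written against this explanation, but that bound averages a whole class. Among 500 genes of like count, FTH1P20 and MT-ND3 were at percentiles 75.4 and 77, GNG5P2, RPL37 and RP11-543P15.1 at 96.6, 98.4 and 98.8, and SCDP1 at 100 (222 against a median of 5.8), so that shared reads stay open, and a biological difference between the arms stays open and untested.

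Few genes were called with E2 or fulvestrant (0 to 5 per contrast by edgeR as reported and up to 50 with no filter on low counts, with 592 to 1665 at an unadjusted p under 0.05, and 0 to 15 by DESeq2). Too few libraries or counts stays open as a cause. The same design called 2155 genes with a change under 1.5-fold between the arms in DMSO. With 3268 genes called there, the adjusted p threshold was easier to reach than where few genes change, so that this test cannot decide. In simulated data 60% of 1.5-fold changes were recovered for E2 in shNC and 44% for the difference of the E2 effect. Of 4-fold changes 96% were recovered in both. These simulations changed 200 genes at once, each with a mean of at least 1 CPM, which also eased the threshold. They show power for 4-fold changes only where as many genes change, and recovery may be lower where few do. Little estrogen receptor transcript is a candidate explanation, with ESR1 at most 1.08 CPM, although protein was not measured. Mixed-up treatment labels cannot be told apart from this: 3 of 14 other assignments of the shNC libraries into pairs called 50 or more genes (449, 250 and 183, against 2 as labelled). Each of the 3 joined the replicate 1 libraries of DMSO and E2, and the highest also joined their replicate 2 libraries, so that it split DMSO and E2 by replicate number; after GC correction the highest was 37 in shNC and 56 in shARID1A (28 before), and with a replicate block E2 against DMSO in shNC called 4 genes.

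More genes were called between the arms with E2 (4633) than in DMSO (3268), a ratio of 1.418. Depth as the whole cause was argued against, since the ratio was 1.336 with all libraries thinned to the lowest total. After GC correction it was 1.223, between the bounds set for and against that explanation. Larger knockdown effects with E2 could contribute, with a mean 1.114 times that in DMSO (bootstrap over genes 1.084 to 1.139), but 1.048 after GC correction, so that this stays open.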

How the results depend on the processing

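The tests with GC correction, with the replicate block and GC correction, and without 2 libraries were chosen after the results were seen. ARID1A in the knockdown and the mesenchymal and matrix list kept their direction and side of the threshold under all settings run, and the knockdown counts moved by over 1.5 times under the settings given below only. Of the named genes 7512 values were the same, 340 lost their call and 0 reversed. The same values include ARID1A, ESR1 and GREB1 where they were never called. Apart from ESR1 and GREB1, the 1.5-fold test lost 182 of 273 values in knockdown contrasts and 9 of 22 in treatment contrasts. The legacy dispersion lost 1 and 3. In most fits without 1 library, treatment contrasts lost a larger share than knockdown contrasts. Of the lists 533 values were the same and 87 lost their call. Counts that moved by over 1.5 times follow, for E2 against DMSO in shNC and in shARID1A and the difference of these (a, b, c), E2 plus fulvestrant against E2 likewise (d, e, f), and E2 plus fulvestrant against DMSO in shNC and shARID1A (g, h). As reported, a to h were 1, 4, 5, 1, 1, 2, 2 and 0. DESeq2 size factors gave b 1, and upper-quartile factors c 8. The DESeq2 Wald test gave c 15, d 2, e 13, f 1 and g 13, with 0 reversed by fulvestrant. No filter on low counts gave a to h as 12, 37, 41, 19, 41, 9, 50 and 12, with 8 reversed and a median knockdown log2 fold change of E2-called genes of 1.41. A filter at CPM of at least 1 in 2 libraries gave f 1. Only libraries of the groups compared gave a 7, b 21, c 19, g 11 and h 1. The replicate block gave a 4, c 12 and g 4, and the legacy dispersion b 1 and f 1. Tested against 1.5-fold, b was 0, c 1, f 1 and g 0, and the knockdown counts 308, 336 and 327 in DMSO, E2 and E2 plus fulvestrant, by construction of a stricter test. GC correction gave b 10, c 23, d 4, e 2 and g 8, with 2 reversed. The replicate block with GC correction gave a to g as 11, 19, 30, 8, 3, 4 and 19, with 4 reversed and a median of 0.019 for E2-called genes under the knockdown. Camera with an estimated correlation called 5 lists in place of 31. For all but the 1.5-fold test the cause was not tested. Without shNC E2 plus fulvestrant replicate 2 and shARID1A E2 replicate 2 together, b was 0, c 3, d 6, g 10 and h 1, the knockdown counts 2754 with E2 and 2535 with E2 plus fulvestrant, the median E2 log2 fold change in shARID1A of genes called in shNC -0.601 (0.159 as reported) and the median of E2-called genes 4.629. Leaving out 1 library, with the lone library assumed to vary like the other groups, gave ranges of 1 to 4 (a), 0 to 5 (b), 3 to 18 (c), 1 to 6 (d), 1 to 27 (e), 1 to 5 (f), 0 to 10 (g) and 0 to 4 (h). The knockdown counts ranged over 2026 to 3370 in DMSO, 2770 to 4702 with E2 and 2336 to 4237 with E2 plus fulvestrant, and their overlap over 1552 to 2152. The median E2 log2 fold change in shARID1A of genes called in shNC ranged from -0.601 to 0.591, the reversed genes from 1 to 3, the median of E2-called genes from 2.484 to 10.232 and the called lists from 24 to 32. Replicate 1 minus replicate 2 correlated at -0.222 to 0.276 between groups over 15 pairs of groups (-0.084 to 0.133 after GC correction), which left open whether replicate numbers pair libraries. Within shNC, genes of low GC content were higher in replicate 2 than in replicate 1 in 3 of 3 groups (-0.026 and 0.085, -0.006 and 0.113, 0.115 and 0.205 for replicates 1 and 2 in DMSO, E2 and E2 plus fulvestrant). Within shARID1A they were lower in replicate 2 in 2 of 3 groups (-0.022 and -0.086, -0.097 and -0.201, -0.078 and 0.018). Over all groups the log2 deviation of these genes was also lower in shARID1A, with ranges that overlapped, at -0.026 to 0.205 in shNC and -0.201 to 0.018 in shARID1A. The share of counts in the 10 most abundant genes was 6.6 to 6.84% and 7.3 to 7.53%, respectively. With GC correction no list called by camera between the arms lost its call. Fry called 43 lists where camera called 31. Depth left 3 counts at 0.0776 to 0.104 CPM as the limit for a gene at 0, or double that if each read pair was counted as 2 reads.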

Other observations

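The tests of odd and even counts, of a shared E2 response and of copy number were all chosen after the results were seen.

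The 7 genes below were not named above, differed between the arms in all 3 treatments, and were chosen after their values were seen. P2RY6, a receptor gene for UDP, rose by 1.86, 1.86 and 1.62 on the log2 scale in DMSO, E2 and E2 plus fulvestrant (9.71 ± 1.22 to 33.3 ± 2.05 CPM, SD, 6 libraries of each arm), and PLCG2, a phospholipase C gene, by 1.57, 1.85 and 1.67. PKDCC, which encodes a secreted tyrosine kinase, rose from 7.61 to 26.0 CPM and the atypical kinase gene MAPK4 from 7.69 to 25.5 CPM. LGR6, a receptor gene for R-spondins, had log2 fold changes of -2.32, -2.07 and -3.05, and PTPRE, a tyrosine phosphatase gene, fell from 9.55 to 1.37 CPM. The chondroitin sulfotransferase gene CHST11 had log2 fold changes of -2.57, -2.22 and -2.49.

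Counts of 2, 4 and 6 were each more frequent than counts of 1, 3 and 5 in 12 of 12 libraries. Both mates of read pairs counted as separate reads is a candidate explanation, which would make the counting error larger than that of single reads.

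The E2 log2 fold changes of the arms correlated at -0.108 over 10338 genes after GC correction, while 8 other splits reached 0.133 in size. A response to E2 shared by both arms under the threshold may therefore exist or not, and this test did not decide it.

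Copy number could differ between the arms, but a difference over a large region as the cause of the many changed genes was argued against. The largest median knockdown log2 fold change of 60 neighbouring genes was 0.141 in 7467 windows, the lowest -0.1, over the 8824 genes (85.4%) whose order RefSeq gives.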
